A study of Mus musculus with 12 samples.

How the data were processed

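The series holds 12 RNA-seq libraries of mouse bone marrow mesenchymal stem cells, stromal cells that can become fat, bone or cartilage cells. Per the labels, the cells came from female C57BL/6 mice and were taken at passages 9 to 10. All cultures received an adipogenic cocktail of 0.5 mM isobutylmethylxanthine, 1 uM dexamethasone and 5 ug/mL insulin for 14 days, together with 0.1% DMSO (the vehicle), 500 nM rosiglitazone (ROSI) or 50 nM tributyltin (TBT), with 4 libraries per treatment. Per the labels' protocols, ribosomal RNA was depleted and libraries were read as single 50 nt reads on a SOLiD sequencer without strand information. Reads of a gene and of an overlapping or antisense gene therefore could not be told apart.

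The authors deposited a table of raw read counts per gene symbol, with 23955 symbols and 1 column per library, and a table of regularized-log values on a log2 scale. Per the submitters' processing notes the genome build was mm9, and FastQC, SAMtools and DESeq2 were used, with no versions given. The aligner, the counting program and the gene annotation are not given in the sources used here. Both tables have 12 sample columns, which were mapped to groups and replicates by the library titles. The counts were the basis of all tests, and the deposited log2 values entered 1 alternative only.

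Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 3 groups, which left 12323 genes. Library sizes were scaled with TMM factors, 1 quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 12 libraries without covariates, and each pair of groups was contrasted. P-values were adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors were derived as the log2 fold change divided by the root of its F statistic. CPM below means a count divided by the TMM-scaled library size, as the cpm function of edgeR gives it, given as mean ± SD over n = 4 libraries. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. No 2 libraries of a group were copies: a chi-square over genes with at least 10 counts in the pair was far above its degrees of freedom for every pair, the lowest ratio being 4.81.

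Before the data were examined, 28 gene lists with 507 genes in all were fixed from textbook knowledge of adipocytes, nuclear receptors and other cell types that a marrow culture can hold. Lists were tested on log2 CPM values (prior count 2) with camera from limma 3.58.1 with a preset correlation of 0.01, which compares a list with all other genes, and the p-values were adjusted over the 27 lists that had at least 2 tested members. The same test with a correlation estimated from the data and fry, which asks only whether a list moves on balance, were run beside it. With the estimated correlation, 11 of 22 calls held in ROSI against DMSO, 0 of 10 in TBT against DMSO and 0 of 16 in TBT against ROSI; fry, which compares a list with no other genes, called 24, 12 and 19 lists. Counts adjusted over the list alone use only the list's own members. Lists share members, such as Scd1, Plin4 and Angptl4, and are not independent of each other.

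Genes named in the text followed a rule fixed before the data were examined. In each comparison these were the 6 largest positive and the 6 largest negative log2 fold changes among genes past the threshold whose libraries did not overlap between groups and whose mean was at least 5 CPM, the 3 members with the smallest p in the direction of each list that camera called, and 16 fixed genes: Pparg, Rxra, Rxrb, Rxrg, Cebpa, Fabp4, Adipoq, Plin1, Slc2a4, Lep, Retn, Cfd, Ucp1, Cidea, Abca1 and Srebf1. For a list without a call, up to 3 members with the smallest p are named. Some genes that the rule picks are not reported here, though they are part of all counts. Genes named outside the rule were chosen after their values were seen, and the text says so.

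The scripts were tested on simulated counts drawn from the real means and library sizes. In the simulated ROSI against DMSO comparison, with 12323 genes, 20.9% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 97.0% of those changed 4-fold were recovered. For TBT against DMSO these shares were 31.3%, 67.2% and 90.9%, and for TBT against ROSI 26.9%, 76.1% and 97.0%. In these 3 simulations 9 of 127, 1 of 127 and 6 of 139 calls were false. A planted list was recovered and 0 other lists were called. Genes were simulated independently of each other, while the estimated correlation reached 0.58 in the real endoplasmic reticulum stress list. False list calls that come from such correlation were therefore not tested.

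The alternatives chosen before the data were examined were DESeq2 size factors or upper-quartile factors in the edgeR fit, DESeq2 1.42.0, no filter, a mean of at least 5 CPM, a replicate block, a fit of only the 2 groups compared, an adjusted p under 0.01, glmTreat against a fold of 1.2, limma on the deposited log2 values, DMSO libraries split between the ligands and each library left out in turn. Chosen after the data were seen were a correction for GC content with a spline of 4 degrees of freedom per library, counts without Rn45s and Malat1, genes at least 5 times above a background measured on sensory receptor genes, and GC correction with TBT replicate 4 left out. GC content and transcript length came from GENCODE mouse release 21, matched by symbol for 98.5% of the symbols, with no coordinates used. Other splits of the 8 libraries of each comparison were refitted, all 35 of them.

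Library totals ranged from 4027152 to 7474654 counts. Reads carry no molecular identifiers, so limits from a count of 0 cover counting error only. A count of 0 over the 4 TBT libraries allows up to 3 counts or 0.143 CPM. Genes with near-identical copies, such as Scd1 and Scd2, the Ifit, Oas, Gbp and Iigp families, C1s1 and C1s2, and Pnp2, are uncertain, since the counting rule for shared reads is not known.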

Results

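Gene expression was measured in mesenchymal stem cells from mouse bone marrow after 14 days of adipogenic induction with vehicle (DMSO), 500 nM rosiglitazone (ROSI) or 50 nM tributyltin (TBT), with 4 libraries in each group. Rosiglitazone is a ligand of the fat-cell receptor PPARγ. Tributyltin is an organotin compound that binds the retinoid X receptors (RXR) as well as PPARγ. The title of the series places the study in RXR activation during adipogenesis. Library totals are given with the processing, and 12323 of 23955 gene symbols were tested.

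**Figure D1:**
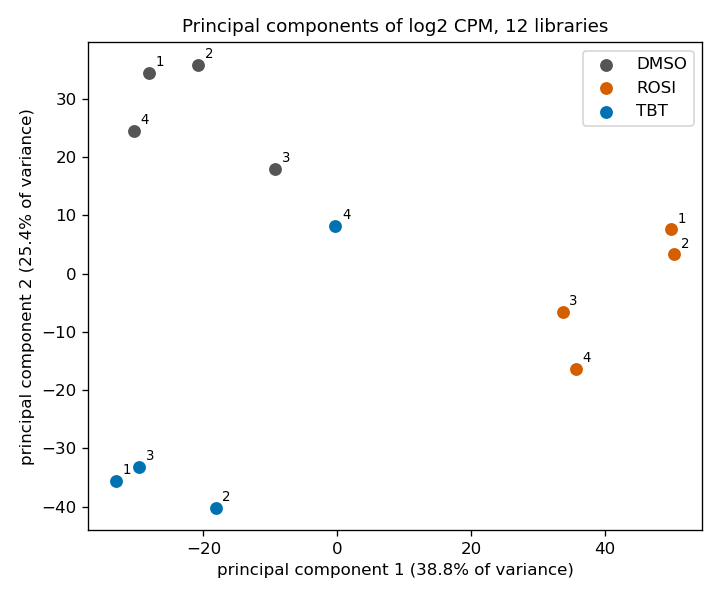
Scatter plot of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by group and numbered by replicate. Component 1 held 38.8% of the variance and component 2 held 25.4%, and TBT replicate 4 lies apart from TBT replicates 1 to 3.

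The ROSI libraries lay apart from the others on the first principal component, and TBT replicates 1 to 3 lay apart on the second. TBT replicate 4 correlated with its own group at a mean r of 0.953, across genes, and with the DMSO libraries at 0.961. Rn45s, the precursor of ribosomal RNA, took 6.85% of counts in TBT replicate 4 and 0.399% to 0.670% in the other TBT libraries. In TBT replicates 1, 2 and 3 the fifth of genes richest in GC lay below the fifth poorest in GC by a median difference of -0.55, -0.44 and -0.26 on the log2 scale, against 0.11 in TBT replicate 4. Reads on 1510 sensory receptor genes, which are silent in most tissues, made up 531.5 ± 228 CPM in DMSO, 70.2 ± 7.16 in ROSI and 143 ± 36.1 in TBT (without TMM scaling, SD, n = 4).

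The first comparison asks what rosiglitazone changed in cells under the adipogenic cocktail. Fat-cell genes rose and interferon-response genes fell: Fabp4, the fatty acid carrier of fat cells, went from 147 ± 114 CPM in DMSO to 1163 ± 93.4 in ROSI (SD, n = 4), while Ifi44, an interferon-induced gene, went from 238 ± 137 to 12.5 ± 0.984. In all, 2787 genes passed the threshold, 1237 higher and 1550 lower in ROSI (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Of these, 397 rose and 785 fell by at least 2-fold. Background reads in DMSO, described below, may add to the falls, and their part in this imbalance was not tested.

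**Figure D2:**
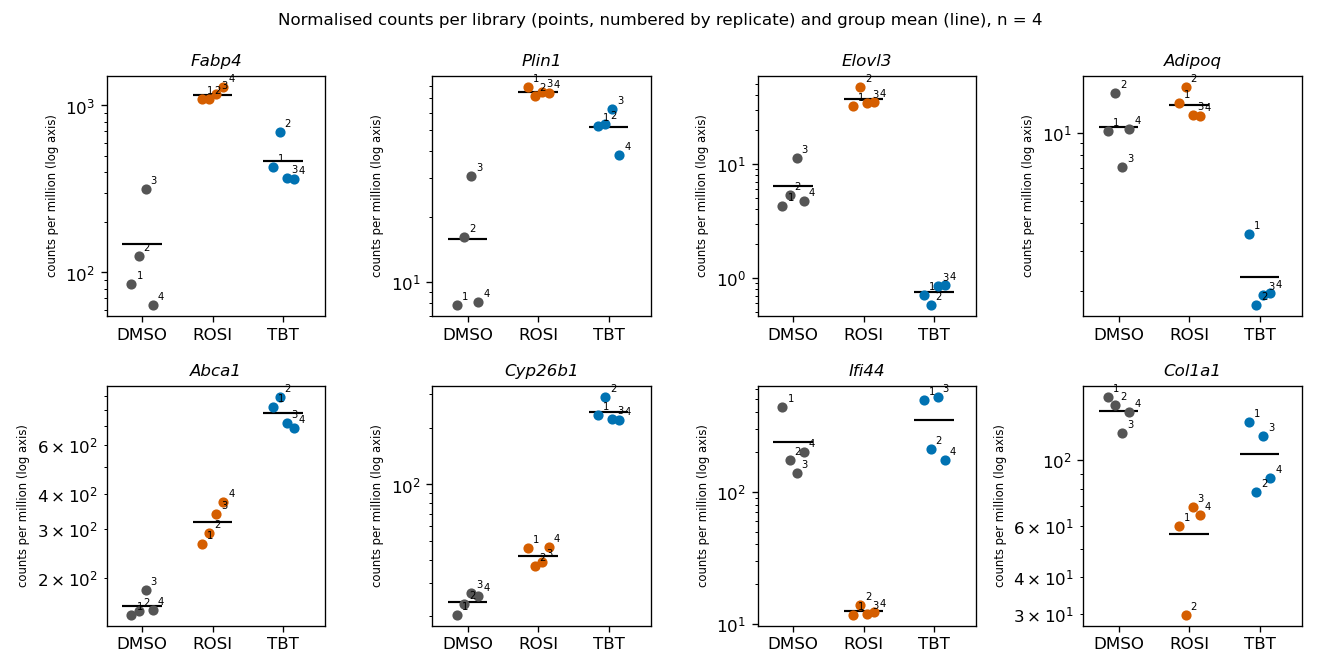
CPM (log axis) of 8 genes in each library of the 3 groups. Points are libraries, numbered by replicate, and lines are group means; Fabp4 averaged 147 in DMSO, 1163 in ROSI and 464 in TBT, and Elovl3 averaged 6.43, 37.3 and 0.755.

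Among 24 tested adipocyte genes, 19 rose and 1 fell with ROSI (20 and 1 adjusted over the list alone). Acsl1, which activates long-chain fatty acids, rose by 2.08 ± 0.22 (log2 fold change ± SE), Plin4, a lipid droplet coat protein, by 1.46 ± 0.17, and Dgat2, which makes triglycerides, by 2.55 ± 0.30. The list was called by camera (adjusted p = 1.4e-14) and held with an estimated correlation (adjusted p = 0.038). Of 17 lipid droplet and lipolysis genes, 16 rose (16 adjusted over the list alone). Plin2 was at 2.13 ± 0.21 and Mgll, a monoglyceride lipase, at 2.03 ± 0.20. Of 16 PPAR targets, 14 rose and 1 fell (15 and 1 adjusted over the list alone). Angptl4, an inhibitor of lipoprotein lipase, was at 2.04 ± 0.21 and Pdk4 at 1.56 ± 0.17. Plin1 rose by 2.22 ± 0.31, Cebpa, a transcription factor of fat-cell differentiation, by 1.32 ± 0.19, Slc2a4, the insulin-regulated glucose transporter, by 2.34 ± 0.43, and Retn by 1.57 ± 0.29. Adipoq, which encodes adiponectin, differed by 0.34 ± 0.24 and did not pass the threshold (edgeR adjusted p = 0.34), nor did Pparg itself (0.41 ± 0.15, edgeR adjusted p = 0.066), Rxra (0.36 ± 0.14, 0.068) or Rxrb (0.58 ± 0.28, 0.15). Without 1 library, Pparg passed in 3 of 12 fits, Rxra in 2 and Rxrb in 1. Of 9 other alternatives, 2 called Pparg and 1 called Rxra.

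Lipid synthesis and oxidation genes rose as well. Of 19 lipogenesis genes, 15 rose (17 higher and 1 lower adjusted over the list alone), including Scd1, which desaturates fatty acids, from 2317 ± 1230 to 11220 ± 893 CPM, and Scd2 by 1.26 ± 0.16. Of 19 fatty acid oxidation genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone). Acadm was at 1.69 ± 0.19 and Hadhb at 1.75 ± 0.19. Of 19 genes of the TCA cycle, 17 rose (18 adjusted over the list alone). Cs, citrate synthase, was at 1.16 ± 0.14 and Idh3g at 0.89 ± 0.14. These 3 lists and the lipid droplet and PPAR target lists held with an estimated correlation (adjusted p = 0.038). Of 12 tested brown and beige fat genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.038 with an estimated correlation). Elovl3, a fatty acid elongase, was at 2.49 ± 0.25, Ppara at 1.73 ± 0.24 and Cox8b at 3.12 ± 0.48. Cox8b had only 11 counts over the DMSO libraries (0.51 ± 0.37 CPM). Cidea rose by 0.80 ± 0.26 (edgeR adjusted p = 0.031), a call that ended without DMSO replicate 1, 3 or 4 or without ROSI replicate 1 or 2, with an adjusted p of up to 0.092. Ucp1, the uncoupling protein of brown fat, was too low to test, at 0.37 ± 0.54 CPM in DMSO and 0.42 ± 0.25 in ROSI.

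Of 37 respiratory chain genes, 18 rose (20 adjusted over the list alone). Cycs, cytochrome c, was at 1.62 ± 0.16, Atp5b at 1.09 ± 0.18 and Sdha at 0.92 ± 0.15. This list had an adjusted p of 1.3e-08 with the preset and of 0.056 with an estimated correlation. Of 18 glycolysis and hypoxia genes, 13 rose (15 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Vegfa was at 1.64 ± 0.18, Hk2 at 1.62 ± 0.19 and Pfkp at 1.24 ± 0.19. Of 15 genes of the endoplasmic reticulum stress response, 13 rose (13 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation). Dnajb9 was at 1.46 ± 0.18, Atf3 at 1.82 ± 0.26 and Hyou1 at 1.26 ± 0.20. Of 11 LXR targets 6 rose (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.056 with an estimated correlation), among them Abca1, a cholesterol exporter, at 1.00 ± 0.14 and Srebf1 at 1.21 ± 0.20. Of 11 adipokines 7 rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.056 with an estimated correlation). Apln was at 1.33 ± 0.19 and Rbp4 at 2.60 ± 0.42, from a low 1.32 ± 0.85 CPM in DMSO. Cfd was at -0.82 ± 0.28, a call that 8 of the 12 libraries each ended when left out (DMSO replicates 1, 2 and 4, all ROSI replicates and TBT replicate 3), with an adjusted p of up to 0.16. Cholesterol synthesis (5 of 20 higher and 1 lower, the same adjusted over the list alone, with Lss at 1.35 ± 0.18, Insig1 at 1.32 ± 0.18 and Cyp51 at 0.98 ± 0.17) and insulin signalling (8 of 22 higher and 4 lower, 9 and 4 adjusted over the list alone, with Pde3b at 0.95 ± 0.15, Trib3 at 2.24 ± 0.39 and Irs1 at 0.89 ± 0.16) were called at a camera adjusted p of 0.037 each and not with an estimated correlation (adjusted p = 0.10 and 0.14). The cholesterol synthesis call ended without ROSI replicate 1 (adjusted p = 0.084) or 3 (adjusted p = 0.050) and after GC correction (adjusted p = 0.054), and the insulin signalling call without DMSO replicate 2 (adjusted p = 0.061).

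All 30 interferon-response genes tested fell with ROSI (30 adjusted over the list alone), with a median log2 fold change of -3.03 (camera adjusted p = 1.4e-26, and adjusted p = 0.038 with an estimated correlation). Oasl2 fell from 277 ± 82.4 to 20.98 ± 4.64 CPM, Gbp3 from 45.1 ± 14.1 to 2.65 ± 0.797 and Ddx58, a sensor of viral RNA, from 151 ± 46.7 to 31.3 ± 5.88. The 6 largest decreases under the naming rule were I830012O16Rik (-4.99 ± 0.44), Zbp1 (-4.67 ± 0.46), the collagen gene Col24a1 (-4.53 ± 0.37), Iigp1 (-4.40 ± 0.39), F830016B08Rik (-4.35 ± 0.42) and Ifi44 (-4.25 ± 0.41). Interferon-induced genes among them include Zbp1, Iigp1 and Ifi44. In the same libraries the sensory receptor reads were 70.2 CPM in ROSI against 531.5 CPM in DMSO. Of 18 inflammation genes, 9 fell (10 adjusted over the list alone; adjusted p = 0.038 with an estimated correlation). Hp, haptoglobin, was at -1.81 ± 0.16, Il1rn at -1.53 ± 0.20 and complement factor C3 at -1.25 ± 0.16.

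Cell cycle and smooth muscle lists were lower with ROSI, while other mesenchymal lists lost their call with an estimated correlation. Of 23 cell cycle genes, 14 fell (16 adjusted over the list alone). Top2a was at -1.68 ± 0.18, Mki67 at -2.23 ± 0.30 and Ccnb1 at -2.40 ± 0.37, and of 11 smooth muscle genes 7 fell (9 adjusted over the list alone). Acta2 was at -1.02 ± 0.16, Cnn1 at -1.49 ± 0.23 and Tpm1 at -0.80 ± 0.12; both lists held with an estimated correlation (adjusted p = 0.038). Of 30 extracellular matrix genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). Dcn was at -2.15 ± 0.19, Lum at -2.46 ± 0.25 and Ctgf at -2.02 ± 0.21. Of 7 osteoblast genes 5 fell (7 adjusted over the list alone; adjusted p = 0.056 with an estimated correlation), among them Spp1 (-2.12 ± 0.21), Omd (-1.78 ± 0.24) and Col1a1 (-1.39 ± 0.22). Of 14 stromal progenitor genes 5 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation). Pdgfra was at -1.54 ± 0.15, Pdgfrb at -0.90 ± 0.14 and Ly6a at -2.87 ± 0.30; this call ended without DMSO replicate 2 (adjusted p = 0.054). Of 7 chondrocyte genes 2 fell, Col11a1 (-1.44 ± 0.13) and Sox5 (-0.71 ± 0.17), while 3 were lower and 1 higher adjusted over the list alone (adjusted p = 0.12 with an estimated correlation), and this call ended without ROSI replicate 4 (adjusted p = 0.068) or TBT replicate 3 (adjusted p = 0.066). The 6 largest increases under the naming rule (no overlap between groups, a mean of at least 5 CPM) were in Tusc5 (3.42 ± 0.52), Rdh16, a retinol dehydrogenase (3.19 ± 0.46), Ephx2, an epoxide hydrolase (3.17 ± 0.38), Slc25a34 (3.08 ± 0.35), Sptlc3 of sphingolipid synthesis (3.04 ± 0.34) and Chchd10 (3.00 ± 0.64). These folds and their order depended on DMSO replicate 3. Without it the log2 fold changes were 5.06 for Tusc5, 4.64 for Rdh16, 4.21 for Ephx2, 3.79 for Slc25a34, 3.92 for Sptlc3 and 5.72 for Chchd10, and those of Fabp4 and Plin1 were 3.68 and 2.84.

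Lists that camera did not call in this comparison were retinoid targets (2 of 12 higher and 4 lower, with Rarb at -2.17 ± 0.23 and Aldh1a1 at -1.23 ± 0.21), metal and oxidative stress (6 of 18 higher and 2 lower), nuclear receptors (2 of 14 higher and 2 lower), macrophage (1 of 3 higher) and endothelial genes (1 of 4 higher and 1 lower). Adjusted over the list alone these were 2 and 4, 6 and 2, 4 and 2, 1 and 1, and 1 and 1. Fry called the retinoid targets lower (adjusted p = 0.0020) and metal and oxidative stress higher (0.040) in ROSI. Only 1 erythroid gene, Alas2, was tested (-0.73 ± 0.24). Leptin (Lep) counts were below the filter in all groups, at 0.70 ± 0.20 CPM in DMSO, 0.063 ± 0.13 in ROSI and 0.11 ± 0.12 in TBT, and so were those of Rxrg (0.24 ± 0.33, 0.31 ± 0.22 and 0.15 ± 0.099).

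The second comparison asks the same of tributyltin. The gene with the smallest p was Cyp26b1, which degrades retinoic acid, at 24.0 ± 2.77 CPM in DMSO and 242 ± 34.1 in TBT (log2 fold change 3.33 ± 0.15, edgeR adjusted p = 3.6e-10). Abca1 rose from 158 ± 15.1 to 781 ± 94.2 CPM and Angptl4 from 49.0 ± 19.5 to 418 ± 66.9, while Adipoq fell from 10.7 ± 3.26 to 2.30 ± 0.856. In all, 1879 genes passed the threshold, 1013 higher and 866 lower (192 and 317 by at least 2-fold). Without TBT replicate 4 the count was 4124, of which 1850 were among the 1879, and with GC-corrected offsets as well it was 3523.

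Fat-cell genes went both ways. Of 24 adipocyte genes, 9 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 1.0e-04, and adjusted p = 0.38 with an estimated correlation). Those that rose included Rbp4, a retinol carrier (3.82 ± 0.40, from 1.32 ± 0.85 CPM in DMSO), Plin4 (1.31 ± 0.17), Fabp5 (2.22 ± 0.38) and Fabp4 (1.65 ± 0.36), and those that fell included Adipoq (-2.17 ± 0.29) and Cfd, adipsin (-1.90 ± 0.31). Of 17 lipid droplet genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation). Mgll was at 1.56 ± 0.20 and Plin1 at 1.69 ± 0.31 higher and Cidea at -1.84 ± 0.33 lower. Of 16 PPAR targets, 9 rose (10 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). Angptl4 was at 3.08 ± 0.22, Pdk4 at 1.47 ± 0.17 and Cpt1a, which brings fatty acids into mitochondria, at 1.13 ± 0.19. Of 19 fatty acid oxidation genes, 11 rose (14 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). Ech1 was at 1.08 ± 0.17 and Etfa at 0.97 ± 0.16. Of 19 lipogenesis genes, 10 rose (12 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). Scd1 was at 2.30 ± 0.27, Lpin1 at 1.13 ± 0.16 and Scd2 at 1.07 ± 0.16.

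Of 20 cholesterol synthesis genes, 8 rose with TBT (8 adjusted over the list alone; camera adjusted p = 1.0e-04, and adjusted p = 0.074 with an estimated correlation). Idi1 was at 1.41 ± 0.20 and Insig1 at 1.15 ± 0.18. Of 18 glycolysis and hypoxia genes, 8 rose (11 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation). Pgam1 was at 1.39 ± 0.21, Pgk1 at 1.44 ± 0.24 and Pdk1 at 1.38 ± 0.24. Of 11 LXR targets, 5 rose and 2 fell (6 and 3 adjusted over the list alone). Abca1 was at 2.31 ± 0.14 and Lpcat3 at 0.58 ± 0.11. The camera adjusted p was 0.043, and the adjusted p was 0.43 with an estimated correlation. The call ended without TBT replicate 4 (adjusted p = 0.29), DMSO replicate 4 (0.074) or ROSI replicate 2 (0.053). Of 18 inflammation genes, 8 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). Hp was at -1.65 ± 0.15, Lcn2 at -1.19 ± 0.19 and Il1rn at -1.19 ± 0.19. Of 23 cell cycle genes, 4 fell (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.37 with an estimated correlation). Tyms was at -0.96 ± 0.15, Mcm2 at -0.53 ± 0.16 and Bub1b at -0.78 ± 0.24, and the camera call ended without TBT replicate 4 (adjusted p = 0.14) or DMSO replicate 4 (0.13). The gene calls of Mcm2 and Bub1b each ended when any of DMSO replicates 1, 3 and 4 or TBT replicates 1 and 3 was left out, with edgeR adjusted p of up to 0.11; that of Bub1b also ended without DMSO replicate 2 or TBT replicate 2.

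The interferon list differed little from DMSO in its median (-0.11), with 4 of 30 members lower (4 adjusted over the list alone; camera adjusted p = 0.17). Camera called it lower without DMSO replicate 3 (adjusted p = 0.011), TBT replicate 1 (0.046) or TBT replicate 3 (0.020). Other lists without a camera call were brown and beige fat (1 of 12 higher and 2 lower), the respiratory chain (5 of 37 higher and 2 lower), the TCA cycle (3 of 19 higher), retinoid targets (2 of 12 higher, Cyp26b1 and Dhrs3 at 0.55 ± 0.13, and 1 lower), extracellular matrix (3 of 30 higher and 7 lower), smooth muscle (2 of 11 higher) and endoplasmic reticulum stress (2 of 15 lower). Adjusted over the list alone these were 2 and 2, 6 and 2, 7 and 0, 3 and 1, 4 and 10, 3 and 0, and 0 and 2. Insulin signalling (4 of 22 higher and 3 lower), adipokines (4 of 11 and 3), osteoblast (1 of 7 lower), chondrocyte (1 of 7 lower), stromal progenitor (3 of 14 lower), metal and oxidative stress (3 of 18 higher and 2 lower) and nuclear receptor genes (2 of 14 higher and 1 lower) were not called either, with the same counts adjusted over the list alone, and 0 of 3 macrophage and 0 of 4 endothelial genes passed the threshold. Among the largest other changes were increases in 2610528A11Rik (3.29 ± 0.55), Fam107a (2.96 ± 0.28) and Slc25a34 (2.61 ± 0.36), and decreases in Gabra3 (-3.04 ± 0.33), the matrix protease Mmp2 (-2.35 ± 0.25), Pnp2 (-2.30 ± 0.20) and Tspan11 (-2.21 ± 0.16). Without 1 library, camera also called the extracellular matrix list (in 4 of 12 fits, lowest adjusted p = 0.019), the TCA cycle (3 fits, 0.025), the respiratory chain (2 fits, 0.016) and endoplasmic reticulum stress (2 fits, 0.0024). On all libraries, fry called the retinoid targets (adjusted p = 0.0020) and the adipokines (0.030) higher in TBT. Without DMSO replicate 3 the log2 fold changes were 2.33 for Fabp4, 3.16 for Fabp5, 2.28 for Plin1 and 3.30 for Slc25a34. Srebf1 rose by 0.70 ± 0.20 (edgeR adjusted p = 0.030), a call that ended without DMSO replicate 1, 2 or 4 or TBT replicate 2 or 3, with an adjusted p of up to 0.082. Pparg (0.36 ± 0.15), Rxra (-0.17 ± 0.14), Rxrb (-0.40 ± 0.29), Cebpa (-0.04 ± 0.20), Slc2a4 (0.63 ± 0.48) and Retn (0.48 ± 0.31) did not pass the threshold. Rxrb passed in 1 of 12 fits without 1 library (edgeR adjusted p = 0.022). Ucp1 had 0 counts in the TBT libraries, which allows up to 0.143 CPM.

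**Figure D3:**
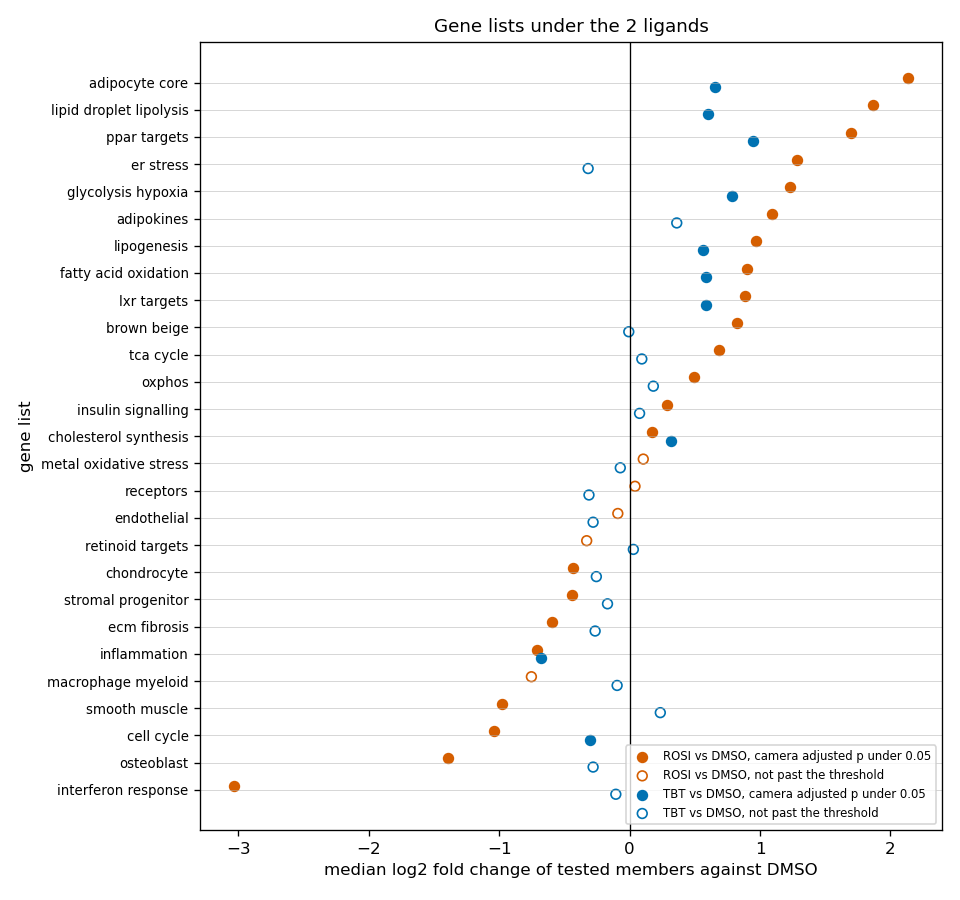
Median log2 fold change against DMSO (x axis) of the tested members of 27 gene lists (y axis), for ROSI (orange) and TBT (blue). Filled points passed the camera test with a preset correlation at an adjusted p under 0.05; the interferon list had a median of -3.03 with ROSI and -0.11 with TBT.

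The third comparison sets the ligands against each other. Of 24 adipocyte genes, 16 were lower and 2 higher in TBT than in ROSI, a list call that did not hold with an estimated correlation (adjusted p = 0.13). Elovl3, of the brown and beige fat list, averaged 0.755 ± 0.137 CPM in TBT and 37.3 ± 6.90 in ROSI, Acsl1 117 ± 3.99 and 860 ± 83.9, and Adipoq 2.30 ± 0.856 and 13.3 ± 1.90. Abca1 (781 ± 94.2 against 315 ± 49.2) and Cyp26b1 (242 ± 34.1 against 42.0 ± 4.93) were higher with TBT. In all, 2940 genes passed the threshold, 1575 higher and 1365 lower in TBT (511 and 421 by at least 2-fold). Without TBT replicate 4 the count was 4826, of which 2881 were among the 2940.

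In the adipocyte list 17 were lower and 2 higher adjusted over the list alone (camera adjusted p = 3.1e-07). Gpd1 was at -2.79 ± 0.35, Fabp4 at -1.32 ± 0.35, Cebpa at -1.36 ± 0.20, Slc2a4 at -1.70 ± 0.41 and Retn at -1.09 ± 0.28 among the genes lower in TBT. Of 17 lipid droplet genes, 12 were lower (13 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Plin2 was at -2.25 ± 0.22, Cidea at -2.64 ± 0.31 and Pnpla2, a triglyceride lipase, at -1.65 ± 0.25, while Plin1 differed by -0.53 ± 0.29 and did not pass the threshold. Plin1 passed in 1 of 12 fits without 1 library (edgeR adjusted p = 0.041). Of 12 brown and beige fat genes, 7 were lower and 1 higher (7 and 1 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), among them Ppara at -2.26 ± 0.25. Of 15 endoplasmic reticulum stress genes, all 15 were lower in TBT (15 adjusted over the list alone; camera adjusted p = 1.0e-11, and adjusted p = 0.11 with an estimated correlation). Hyou1 was at -2.03 ± 0.21, Atf3 at -2.67 ± 0.28 and Chac1 at -2.51 ± 0.33. Of 19 TCA cycle genes, 12 were lower (12 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Cs was at -1.07 ± 0.14 and Idh3a at -0.90 ± 0.15, and of 37 respiratory chain genes 13 were lower (17 lower and 1 higher adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Cycs was at -1.13 ± 0.16, Uqcrc1 at -1.19 ± 0.18, and Atp5b averaged 2081 ± 244 CPM in TBT and 4173 ± 384 in ROSI.

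Lipogenesis (8 of 19 lower and 2 higher, 10 and 2 adjusted over the list alone, with Dgat2 at -1.87 ± 0.29, Acacb at -0.98 ± 0.19 and Agpat2 at -1.61 ± 0.31) and PPAR targets (9 of 16 lower and 2 higher, 10 and 2 adjusted over the list alone, with Acaa1b at -1.63 ± 0.30 and Pex11a at -0.87 ± 0.21) were called lower in TBT with the preset and not with an estimated correlation (adjusted p = 0.38 for each). Fatty acid oxidation (5 of 19 lower and 1 higher, 7 and 1 adjusted over the list alone, with Hadha at -1.18 ± 0.18, Acadm at -0.95 ± 0.18 and Hadhb at -0.83 ± 0.19) and glycolysis and hypoxia (4 of 18 lower, 4 adjusted over the list alone, with Hk2 at -0.96 ± 0.18, Vegfa at -0.77 ± 0.17 and Aldoa at -0.88 ± 0.26) were called at a camera adjusted p of 0.025 each, and at an adjusted p of 0.39 and 0.48 with an estimated correlation. The first of these calls ended without ROSI replicate 4 (adjusted p = 0.054) or TBT replicate 3 (0.081), and the second without ROSI replicate 1, 3 or 4 (adjusted p = 0.052, 0.11 and 0.061) and after GC correction (0.066). Fry called neither list (adjusted p = 0.053 and 0.17). The call of Aldoa ended without ROSI replicate 1 or TBT replicate 1, 2 or 3, with an edgeR adjusted p of up to 0.075.

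Of 30 interferon-response genes, 28 were higher in TBT than in ROSI (30 adjusted over the list alone; camera adjusted p = 1.1e-23, and adjusted p = 0.11 with an estimated correlation). Oasl2 averaged 375 ± 173 CPM in TBT and 20.98 ± 4.64 in ROSI, and Ifi44 351 ± 185 and 12.5 ± 0.984. The 6 largest increases under the naming rule were I830012O16Rik (5.45 ± 0.44), Iigp1 (4.95 ± 0.39), Ifi44 (4.81 ± 0.42), F830016B08Rik (4.76 ± 0.42), Gm4951 (4.60 ± 0.41) and Gbp3 (4.60 ± 0.35). Under the same rule the 6 largest decreases were Tmem45b (-5.84 ± 0.49), Elovl3 (-5.60 ± 0.35), Chchd10 (-3.90 ± 0.71), Cdsn (-3.69 ± 0.50), Sptlc3 (-3.64 ± 0.35) and Rdh16 (-3.42 ± 0.48). Cdsn was at -4.77 without TBT replicate 2, Tmem45b at -7.21 without TBT replicate 3 and Slc2a4 at -2.34 without TBT replicate 4. Tmem45b had only 4 counts over all TBT libraries (0.21 ± 0.30 CPM), so the size of its fold and its rank are uncertain.

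Camera called the smooth muscle, extracellular matrix, osteoblast and cell cycle lists higher in TBT than in ROSI, and 0 of these 4 calls held with an estimated correlation. Of 11 smooth muscle genes, 10 were higher (10 adjusted over the list alone; camera adjusted p = 1.4e-07, and adjusted p = 0.092 with an estimated correlation). Myh11 was at 3.05 ± 0.36, Tpm2 at 1.35 ± 0.17 and Tpm1 at 0.95 ± 0.12. Of 30 extracellular matrix genes, 15 were higher and 3 lower (16 and 4 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation). Dcn was at 1.91 ± 0.19, Ctgf at 2.08 ± 0.21 and Thbs1 at 1.67 ± 0.22. Of 7 osteoblast genes, 5 were higher (6 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Omd was at 2.04 ± 0.24, Spp1 at 1.05 ± 0.20 and Col1a1 at 0.91 ± 0.22, and of 23 cell cycle genes 11 were higher and 2 lower (14 and 3 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Top2a was at 1.46 ± 0.18, Mki67 at 1.70 ± 0.30 and Rrm2 at 1.03 ± 0.21. Of 12 retinoid targets, 4 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.11 with an estimated correlation). Cyp26b1 was at 2.53 ± 0.14, Aldh1a1, which makes retinoic acid, at 1.79 ± 0.21 and Rarb, a retinoic acid receptor, at 1.76 ± 0.23, and this call ended without TBT replicate 4 (adjusted p = 0.066). Rarb averaged 18.7 ± 3.86 CPM in DMSO, 4.06 ± 0.576 in ROSI and 14.0 ± 3.48 in TBT, so its mean in TBT was not above DMSO. Aldh1a1 averaged 1669 ± 637 CPM in DMSO, 710 ± 66.5 in ROSI and 2454 ± 347 in TBT. Rxra (-0.53 ± 0.14, edgeR adjusted p = 0.011) was lower in TBT, a call that GC correction ended (adjusted p of up to 0.10 over the alternatives). Rxrb (-0.99 ± 0.29, edgeR adjusted p = 0.020) was also lower, a call that ended without ROSI replicate 1 or 2 or TBT replicate 1 or 2, with an adjusted p of up to 0.075, and so was Cfd (-1.08 ± 0.32, edgeR adjusted p = 0.024), whose call ended without ROSI replicate 2 or 4 or TBT replicate 1 and after GC correction, with an adjusted p of up to 0.096. Pparg differed by -0.05 ± 0.15 and Srebf1 by -0.51 ± 0.20, and neither passed the threshold. Srebf1 passed in 4 of 12 fits without 1 library and in 1 of 9 other alternatives.

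Lists that were not called between the ligands were cholesterol synthesis (6 of 20 higher in TBT and 2 lower), LXR targets (2 of 11 and 4), adipokines (3 of 11 and 6), insulin signalling (4 of 22 and 6), inflammation (4 of 18 and 2), stromal progenitor (5 of 14 and 1), chondrocyte (2 of 7 and 1), metal and oxidative stress (2 of 18 and 4), nuclear receptors (3 of 14 and 4), macrophage (0 of 3) and endothelial genes (1 of 4 and 1). Camera called the inflammation list without ROSI replicate 2 (adjusted p = 0.024) and above background (0.040), and the stromal progenitor list without TBT replicate 2 (0.047) and after GC correction (0.044). Adjusted over the list alone the counts were 6 and 2, 2 and 6, 3 and 6, 5 and 10, 5 and 2, 5 and 2, 2 and 1, 2 and 4, 4 and 5, 1 and 1, and 1 and 1. Fry called cholesterol synthesis (adjusted p = 0.020) and chondrocyte genes (0.027) higher in TBT. It called insulin signalling (0.011), adipokines (0.011) and metal and oxidative stress (0.029) lower.

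Against DMSO, 368 genes rose with both ligands and 415 fell with both, where independent lists of these sizes would share 102 and 109. Another 20 genes rose with ROSI and fell with TBT, and 26 fell with ROSI and rose with TBT. These 46 opposite calls became 218 without TBT replicate 4 and 214 with GC correction as well, and the shared calls became 1235 and 1261. With the DMSO libraries divided between the ligands, 2 for each, 170 to 490 genes were shared in the same direction. The fold changes of the ligands correlated at r = 0.44 across genes, which are not independent replicates, where 20 simulations of unchanged groups gave a mean of 0.50 from the shared DMSO libraries alone. The covariance was 0.154 against 0.0297 in the simulation, a difference of 0.125, and with the DMSO libraries divided r was 0.36 to 0.53.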

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

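All tests of explanations in this part were chosen after the results were seen, except the test on other silent gene families; the rule that picked single libraries was fixed beforehand.

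A library was picked out when its gap to the nearest of its group took more of the group's range than the 95% critical value of Dixon's test, and chance alone picks about 1 in 20 groups. Of 482 groups tested, 43 were picked. DMSO replicate 3 was high for Tusc5 (52.22 CPM), Rdh16 (24.87), Ephx2 (21.27), Sptlc3 (25.42), Chchd10 (21.14), Elovl3 (11.33), Scd1 (4151), Mgll (35.5), Abca1 (180.3), Fabp5 (31.22), Gpd1 (51.11), Agpat2 (78.05), Pnpla2 (178.2) and Acaa1b (6.493), with a PPAR target score of -0.2315 against -1.20 to -1.07 in the other DMSO libraries. Its mean r with the ROSI libraries was 0.958, against 0.927 to 0.934 for the other DMSO libraries. With the TBT libraries it was 0.963, against 0.946 to 0.950, and with its own group 0.978. Why DMSO replicate 3 lay nearer to the treated libraries was not tested. TBT replicate 4 was high for Atp5b (2444 CPM), Ech1 (86.76), Lcn2 (202), Agpat2 (117), Hadha (108.5), the macrophage score (0.4332) and the Rn45s share (6.851%), and low for Spp1 (117.9 CPM), Top2a (37.18) and Tpm2 (283.8). DMSO replicate 4 stood out for the chondrocyte score (0.3609), Il1rn (460.4 CPM), Tpm1 (516.8) and Tspan11 (40.77), and DMSO replicate 2 for Acta2 (761.1) and Ucp1 (1.17). ROSI replicate 1 stood out for I830012O16Rik (1.003 CPM), Lep (0.2507) and Retn (17.55), ROSI replicate 2 for Elovl3 (47.56) and Atf3 (25.59), and ROSI replicate 4 for Col24a1 (0.2006). TBT replicate 1 stood out for Adipoq (3.574 CPM) and Cfd (1.787), TBT replicate 2 for Ephx2 (44.78), Cdsn (7.334) and the smooth muscle score (0.3032), and TBT replicate 3 for Acsl1 (122.8).

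At 2255 genes TBT replicates 1 to 3 lay apart from both other groups, and over these TBT replicate 4 had a median position of -8.617% on the way from the nearer other group to TBT replicates 1 to 3. The first tests of a wrong label and of mixed RNA came out on the side of these explanations (it lay nearer TBT replicates 1 to 3 at 8 of 29 genes at least 4-fold apart, and its position was -3.794% at these genes and -8.454% at genes under 2-fold apart), and both tests, with their bounds, were replaced after these results and the single genes had been seen. In the later tests it lay over 2-fold beyond all 8 DMSO and ROSI libraries at 19 genes, such as Cyp26b1, and 15 of these were lower ones, against 0 to 2 for a DMSO or ROSI library. The 2255 genes came from a fit that held these 8 libraries and left out TBT replicate 4, which favours genes where the 8 lie close together. The reference of 0 to 2 is therefore too low. The comparison argues only weakly against a wrong label and against mixed RNA as the whole cause, and a small share of mixed RNA stays open. GC content as the whole cause is argued against by 79.54% of the median log2 difference between TBT replicates 1 to 3 and TBT replicate 4 left after its correction (0.714 before, 0.568 after), while 1330 of the 2255 genes still passed in a corrected fit, in a test that replaced one made on the surviving genes alone (-12.76%). A separate library batch of TBT replicates 1 to 3 stays open, since their Rn45s share (0.399% to 0.670%) lay below that of all 9 other libraries (1.36% to 9.27%, with 6.851% in TBT replicate 4) and the labels give no batch, and no biological explanation was tested.

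Reads on sensory receptor genes were 7.566 times as frequent in DMSO as in ROSI. Library size is argued against, since the lowest DMSO library had 3.845 times the receptor reads of the highest ROSI library at overlapping sizes. On 149 genes of other silent families the ratio was 1.972, between the bounds set before that test. More genes were detected in DMSO libraries, at 18767 ± 187 against 16074 ± 530 in ROSI and 16328 ± 584 in TBT (SD, n = 4). The lowest DMSO library had 18537 genes detected, and the highest ROSI or TBT library had 17140. These numbers go with more low-level reads in DMSO, but their cause was not tested. A general background of reads therefore stays open. Of the 1550 genes lower in ROSI, 1384 were called again among genes at least 5 times above that background. Since 11584 of 12323 tested genes passed this filter, most calls had to remain, and their number alone decides nothing about the cause. It shows only that most of these genes lay well above that background. The treatment stays among the open explanations, as untested.

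Interferon-response genes were lower in ROSI than in DMSO, at a summed 340.1 ± 30.47 against 2224 ± 708.4 CPM (SD, n = 4), and TBT had 2418 ± 948. Myeloid cells in the DMSO cultures are argued against by 1.158 CPM for 5 abundant myeloid transcripts together, and GC content by a median log2 fold change of -3.061 after its correction. Background reads are argued against by the size of the fall. At least 5 times above background lay 29 of 30 members, and the list median was -3.03. All 29 were called lower, which adds little, since all 30 members were already called lower among all tested genes. The summed level in TBT also argues against background reads. It was near that of DMSO, while receptor reads were 143 ± 36.1 CPM in TBT and 531.5 ± 228 CPM in DMSO. An effect of rosiglitazone stays a hypothesis, found and tested on the same data. An immune stimulus of the DMSO and TBT cultures was not tested.

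For the gene counts, 1 of the 35 splits of the 8 libraries, the real one, gave as many genes in each comparison: 2787 genes in ROSI against DMSO with 0 in the highest other split, 1879 in TBT against DMSO with 1444, and 2940 in TBT against ROSI with 2248. Each of the last 2 highest splits put TBT replicate 4 with replicates 1 to 3 of the other group, which points to a structure of the libraries. A share of 1 in 35 is the smallest that these splits can give, and it was not adjusted over the comparisons. In mixed splits the treatment difference lies within both sides and widens their spread, so few calls there say little about chance.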

How the results depend on the processing

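The GC correction, the removal of Rn45s and Malat1, the background filter and the GC correction with TBT replicate 4 left out were chosen after the data were seen, and the bound for a moved correlation was changed from 0.1 to its jackknife SD (0.149) after its values were seen.

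Of the named gene calls in ROSI against DMSO, 76 of 78 held under every alternative run per gene. In TBT against DMSO 38 of 41 held, and in TBT against ROSI 59 of 63. Apart from the fixed genes, the named genes were picked from these same data for large folds or small p. Most of their calls therefore had to hold, and these shares say little about the calls in general. Among the named genes and lists, 0 reversed. Not run per gene were limma on the deposited log2 values, glmTreat, the fit of only the 2 groups compared and the mean of at least 5 CPM. An adjusted p under 0.01 and the split DMSO libraries were not applied per gene either. The median log2 fold change of all genes shifted by at most 0.072 with DESeq2 size factors, upper-quartile factors or GC correction, while single genes moved more under GC correction, which ended the calls of Rxra and Cfd between the ligands. Of the named calls, 8 of 78, 4 of 41 and 3 of 63 moved by over 1.5-fold without 1 library, and 12 of these 15 without DMSO replicate 3.

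An adjusted p under 0.01 gave 1713 genes in ROSI against DMSO (698 higher, 1015 lower), 574 in TBT against DMSO (307, 267) and 1355 in TBT against ROSI (766, 589). Testing against a fold of 1.2 gave 769 higher in ROSI, 775 in TBT against DMSO (396, 379) and 1608 in TBT against ROSI (879, 729). These counts fall by construction. With no filter 2352 genes were lower in ROSI. A replicate block gave 1160 genes in TBT against DMSO (630, 530), though same-numbered libraries did not pair (r from -0.432 to 0.138). The block also ended the calls of Cfd and Cidea in ROSI against DMSO. In TBT against DMSO it ended those of Srebf1, Mcm2, Bub1b and the LXR target list. Only the 2 groups in the fit gave 1199 (616 higher). GC correction with TBT replicate 4 left out gave 3523 in TBT against DMSO (1722, 1801), 2170 lower in TBT against ROSI and an overlap of 1261. The overlap of 783 was 267, 375, 170, 401, 206 and 490 with the DMSO libraries split, and the correlation was 0.6544 with no filter and 0.6294 with DESeq2. Except where stated, the cause was not tested.

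Leaving out 1 library gave 2219 to 3537 genes in ROSI against DMSO (939 to 1625 higher, 1278 to 1912 lower), 1019 to 4124 in TBT against DMSO (527 to 2093, 484 to 2031), 1732 to 4826 in TBT against ROSI (949 to 2520, 783 to 2306), an overlap of 454 to 1235 and a correlation of 0.3918 to 0.5462. The highest counts came without TBT replicate 4. With 4027152 counts in the smallest library, 2-fold changes were recovered for 59.7% of simulated genes in ROSI against DMSO.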

Other observations

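The 3 gene lists in this part, their tests and the genes named from them were chosen after the data were seen, and their list p-values were adjusted together with the other 27 lists, over 30 in all.

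Of 15 complement genes tested with ROSI, 11 were lower and 1 higher (11 and 2 adjusted over the list alone; camera adjusted p = 2.2e-09, and adjusted p = 0.034 with an estimated correlation). Serping1, an inhibitor of the first complement component, was at -3.04 ± 0.16 (log2 fold change ± SE) and Cfb, complement factor B, at -2.41 ± 0.17, while Cd59a was at 1.14 ± 0.20. With TBT 9 were lower and 1 higher than in DMSO (10 and 1 adjusted over the list alone; camera adjusted p = 0.0034, and adjusted p = 0.31 with an estimated correlation), with Serping1 at -1.29 ± 0.15. Against ROSI 9 were higher in TBT (10 adjusted over the list alone; camera adjusted p = 4.4e-07, and adjusted p = 0.10 with an estimated correlation).

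Of 25 peroxisome genes, 13 rose and 1 fell with ROSI (15 and 2 adjusted over the list alone; camera adjusted p = 8.5e-06, and adjusted p = 0.034 with an estimated correlation), with Cat, catalase, at 1.43 ± 0.26. With TBT 6 rose (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.29 with an estimated correlation), with Cat at 1.86 ± 0.27. Against ROSI 8 were lower in TBT and 1 higher (the same adjusted over the list alone; camera adjusted p = 0.036, and adjusted p = 0.23 with an estimated correlation). Of 17 circadian genes, 2 rose and 1 fell with ROSI (the same adjusted over the list alone; camera adjusted p = 0.0497, and adjusted p = 0.12 with an estimated correlation), 2 rose and 2 fell with TBT (2 and 3 adjusted over the list alone; camera adjusted p = 0.26), and 2 were lower in TBT than in ROSI (2 adjusted over the list alone; camera adjusted p = 0.43).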
